A study of Caenorhabditis elegans with 5 samples.

How the data were processed

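The series holds 5 single-colour Agilent arrays of total RNA from N2 adult hermaphrodites, 2 of untreated animals and 3 of animals exposed to 40 MPa for 5 min with 30 min of recovery. The sample titles name these times in the other order, 30 min before 5 min. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was extracted with TRIzol and amplified and labelled with cyanine-3.

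Each array came as the scanner software's spot table, deposited by the authors, with spot intensity on a linear scale and no scaling between arrays. Per the file headers, spots were read with Agilent Feature Extraction 11.5.1.1, with spatial and multiplicative detrending on and no local background correction. The submitters' processing notes name version 10.7.3.1 of that software, and the difference was left open. The deposited value table gives log2 values for 34281 probes. Set against the scanner files, each column equalled log2 of the processed signal minus the array's 75th percentile to within an SD of 0.00474, so its scale, centring and direction are known. Its column medians were −2.10 on control 1, −1.93 on control 2, −1.94 on pressure 1, −1.96 on pressure 2 and −1.79 on pressure 3. Header fields gave 3 slides and 3 scans that coincide: slide 1 with control 1, slide 2 with control 2, pressure 1 and pressure 2, and slide 3 with pressure 3.

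Log2 of the processed signal minus the array's 75th percentile over the 43803 non-control spots was used. Outlier-flagged spots, between 4 and 39 per array, were set aside, no spot was saturated, and replicate spots of a probe were averaged, giving 43603 probes. Probe names were matched to the symbols of a RefSeq gene table of assembly WBcel235, used for names only. It named 36296 probes (83.2%), the remaining 7307 probes were not used in the tests, and 1383 probes carried accessions of several loci. Probe coordinates are those of the files, on ce4 (WS170) per the file headers. A probe lies in the transcript it was designed for, and exon and UTR positions are not given in the sources used here. A gene was represented by its brightest probe over the 5 arrays, and 6175 of 20192 genes had over 1 probe. Genes well above background on at least 2 of the 5 arrays were tested, which left out 3681. A gene not well above background on any array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the dim group's mean, where each array of the dim group was raised to the lowest signal among spots well above background.

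Pressure was compared with control in limma 3.58.1 under R 4.3.3 by a linear model and empirical Bayes moderation with trend and robust options off, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Values are log2 fold changes of pressure over control with standard errors. Since slide 2 holds both groups, every value was also computed with slide as a fixed block, which uses slide 2 alone for the contrast and has 1 residual degree of freedom, and with slide as a random block. The list test was camera with a preset correlation of 0.01 on 38 lists of at least 5 measured genes, and was repeated with an estimated correlation and with fry. A gene list's count adjusted over the list alone used the same p-values. Lists were fixed before the data were examined, and some genes sit in more than 1 list. They covered stress responses (cytosolic heat shock, endoplasmic reticulum, mitochondrial, DAF-16 induced and repressed, SKN-1, HIF-1, heavy metal, osmotic), immunity, regulators, protein and RNA homeostasis, cuticle, germline and embryo, tissues and metabolism.

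Genes named in the text follow a rule fixed before the data were examined. It takes genes past the threshold whose groups do not overlap and, where none pass, the 8 lowest-p genes without overlap in each direction. To these it adds the 4 lowest-p members of each list and 24 stress and reference genes.

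Simulated arrays with the real means and spreads, and 200 of 16480 genes changed, were used to test the scripts. Without a slide effect, the fit over all arrays recovered 73.0% of 16-fold, 12.2% of 4-fold and 0.448% of 2-fold changes with a mean of 3.7 false calls per data set. With a slide effect of the size seen here, it recovered 79.4% of 16-fold, 35.5% of 4-fold and 0% of 2-fold changes with 0 false calls. There the fit with slide as a random block recovered 96.5%, 84.5% and 56.4% with 4.9 false calls, and the fixed block recovered 92.6%, 68.5% and 0% with 4. That slide effect had the same correlation in every gene, as the random block assumes. Simulated at the spread within slide 2, the fixed block made 38.9 false calls per data set beside 98.7% of 4-fold changes recovered. Estimated and simulated fold changes had a slope of 1.00 in the fit over all arrays. The list test was simulated with independent genes and no slide effect. There a proteasome list shifted by 1 log2 unit was called in 10 of 10 data sets, and over these data sets 1 call of another list was made. On the real arrays the estimated correlation within the proteasome list was 0.52. The simulation therefore gives no rate of false calls for lists of correlated genes.

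Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter and a filter on all 5 arrays, the mean of a gene's probes, each probe on its own, outlier-flagged spots kept, the 3 treatments of slide, the replicate number as a block, moderation with trend and robust options, the deposited value table, and each array left out in turn. Adding the probes without a gene, and a looser threshold for the fixed block, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.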

Results

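Gene expression was measured in adult hermaphrodites of the wild-type Caenorhabditis elegans strain N2 after a short exposure to high hydrostatic pressure, and in untreated animals. Whole animals were held at 40 MPa for 5 min in a pressure vessel and then kept in liquid medium with bacteria for 30 min before RNA was extracted. The pressure group had 3 arrays and the control group 2. The labels do not say whether the controls passed through the vessel or the liquid medium. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these 5 arrays, which may be technical. Each array carried 43803 non-control spots read in a single colour. The 75th percentile of the processed signal was 1057 on control 1, 675 on control 2, 674 on pressure 1, 764 on pressure 2 and 1051 on pressure 3. Between 71.9% and 80.5% of spots were well above background. The number of arrays limits the precision of every value given here. After dim probes were set aside, 16511 genes were tested. The question the design poses is which transcripts differ within 30 min of a pressure pulse, against the background of known stress pathways such as the heat shock response and the insulin pathway's transcription factor DAF-16.

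The arrays were spread over 3 slides, each scanned on its own. Slide 1 held control 1, slide 2 held control 2, pressure 1 and pressure 2, and slide 3 held pressure 3. Expression of sperm genes separated control 1 from the rest. The median of 70 measured sperm genes, which include the major sperm proteins, was 8.33 log2 units higher on control 2 than on control 1, and 5.57 higher on pressure 3 than on control 1. The major sperm protein gene msp-45 had a log2 level of −2.31 on control 1, between 6.32 and 6.46 on the 3 arrays of slide 2, and 4.64 on pressure 3. Embryo genes ran the other way, with a median 1.79 log2 units lower on control 2 than on control 1. Body wall muscle genes were 0.68 higher and collagens 0.59 higher on control 2. Over all genes, the first principal component held 73.6% of the variance and set the arrays of slide 2 apart from control 1 and pressure 3. Arrays on slide 2 correlated at r = 0.990 to 0.994 across genes, with 1.71% to 3.17% of genes at least 2-fold apart, whichever groups were paired. Arrays on different slides correlated at r = 0.886 to 0.943, with 24.1% to 27.7% of genes at least 2-fold apart. These correlations are across genes, which are not independent replicates.

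Transcripts with the clearest separation between pressure and control included cuticle collagens and genes of unnamed function. The collagen gene col-17 (F11G11.10, probe on chromosome II, 4866490 to 4866549 of the ce4 assembly) was not well above background on control 1 and was 23.8-fold higher on the pressure arrays of slide 2 than on control 2. The cuticle collagen lon-3 (ZK836.1, chromosome V, 12200077 to 12200136) was 7.86-fold higher, with a log2 fold change of 2.97 ± 0.35 (SE, 3 pressure and 2 control arrays). E01G4.6 (chromosome II, 13485479 to 13485538) was 22.7-fold higher, with a log2 fold change of 4.50 ± 0.41. F53F1.6, F35E12.9 and Y58A7A.4, all on chromosome V, were between 4.27-fold and 5.34-fold higher. T09B4.7, a pseudogene in the reference table, and srlf-19 were not well above background on either control and were at least 2.48-fold and at least 2.60-fold higher. On the lower side, the C-type lectin gene clec-96 (ZK39.5, chromosome I, 11159896 to 11159955) and srlf-11 were not well above background on any pressure array and were at least 5.86-fold and at least 1.59-fold lower. The toxin-regulated gene ttm-2 was 2.75-fold lower, with a log2 fold change of −1.46 ± 0.21. The F-box gene fbxa-84 and the claudin-like gene clc-4 were 2.41-fold and 2.26-fold lower, and the F-box gene fbxa-15 had a mean log2 level of −5.19 in control and −6.33 after pressure. The brighter probe of F46B6.13 was not well above background on any pressure array, and its other probe had a log2 fold change of −2.73. K03B8.11, not well above background on pressure 1, had a mean log2 level of −5.69 in control and −7.15 after pressure. None of these 16 genes passed the threshold, and they are the lowest-p genes in each direction whose groups did not overlap.

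No gene passed an adjusted p of 0.05 in limma's moderated test over all 5 arrays, and the lowest adjusted p was 0.579. At an unadjusted p under 0.05 there were 360 genes, 273 of them higher and 87 lower after pressure. With median scaling 150 of 254 were higher, and with quantile normalization 233 of 367. The 360 genes are fewer than the share of 0.05 of 16511 tested genes that unchanged genes would give. In simulated arrays the same fit gave such a p to 4.77% of unchanged genes without a slide effect and 0.90% with one. The count on the real arrays was 177 without pressure 1, 127 without pressure 2 and 488 without pressure 3. Adjusted over the list alone, members passed in 2 of the 38 fixed lists, the collagens and the intestinal immune effectors, with 3 and 1 genes. A plain two-sample test on the same values called 417 genes unadjusted and 0 after adjustment. The groups did not overlap in 3049 genes, 18.5% of those with a value on every array, where chance gives 20%. The mean of 1274 genes was at least 2-fold higher and that of 171 genes at least 2-fold lower after pressure. Within slide 2 the balance was closer, with 158 genes over 2-fold higher and 135 over 2-fold lower on both pressure arrays. With normexp background correction the log2 fold changes of several of the named genes were closer to 0, at 1.88 for col-17, 2.61 for E01G4.6, 1.94 for lon-3 and −0.50 for clec-96. Others of these genes came nearer still to 0 in at least 1 alternative. Their smallest changes were −0.13 for srlf-11, −0.12 for fbxa-15, −0.23 for K03B8.11, −0.37 for clc-4 and 0.26 for T09B4.7.

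Comparison within slide 2, which holds both groups, gave smaller spreads. Its control side is control 2 alone, so the spread comes from pressure 1 and pressure 2, and control 2 is assumed to vary like them. The log2 fold change of col-17 there was 4.57 ± 0.30, that of E01G4.6 was 4.32 ± 0.21 and that of lon-3 was 2.92 ± 0.26 (SE, 2 pressure arrays against 1 control array). With slide as a fixed block, which is the same comparison, limma called 0 genes, with a lowest adjusted p of 0.0505 and 1644 genes at an unadjusted p under 0.05. With slide as a random block (correlation within slides 0.928), limma called 35 genes, 28 higher and 7 lower. They held 12 of the 16 genes above, and 4 collagens, col-17, lon-3, rol-8 and col-79. They also held the lysozyme gene lys-3, at a log2 fold change of 2.51 ± 0.22, the JNK-like kinase gene kgb-2 at 1.03 ± 0.090, the KGB-1-regulated gene kreg-1 at 0.97 ± 0.086 and the cytochrome P450 gene cyp-33C8 at 1.38 ± 0.12. Of these, rol-8, col-79 and kreg-1 were chosen after their values were seen. At that correlation the fit weighs slide 2 most. Its estimates lay near those within slide 2, at 4.63 against 4.57 for col-17 and 2.51 against 2.61 for lys-3. The 35 calls therefore also rest mainly on control 2. For lys-3 the controls were at −3.12 on slide 1 and −4.64 on slide 2, a gap that this fit treats as a slide difference. Over all arrays lys-3 had 1.72 ± 0.51.

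**Figure D1:**
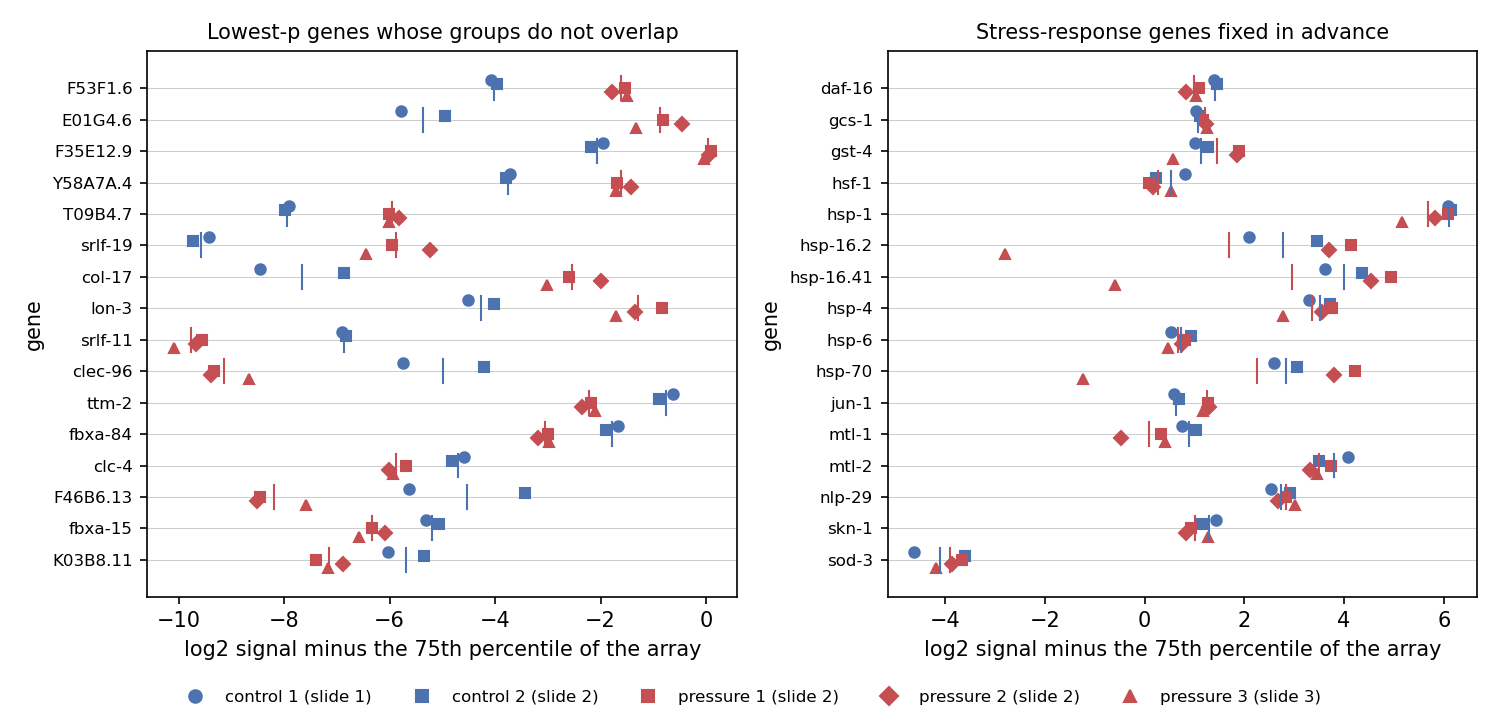
Log2 signal of single genes on each array, relative to the array's 75th percentile. Symbols mark arrays and short vertical lines the group means. Left, the 8 lowest-p genes in each direction whose groups did not overlap, and right, genes fixed in advance. Among the latter hsp-16.2, hsp-16.41 and hsp-70 lie lowest on pressure 3, and jun-1 is higher on all 3 pressure arrays than on both controls.

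The inducible heat shock genes hsp-16.2, hsp-16.41 and hsp-70 were at high signal on both controls and low on a single pressure array. The small heat shock gene hsp-16.2 had log2 levels of 2.09 and 3.46 on the controls, 4.14 and 3.70 on pressure 1 and 2, and −2.79 on pressure 3. The inducible chaperone gene hsp-70 had 2.60 and 3.05 on the controls, 4.22 and 3.80 on pressure 1 and 2, and −1.24 on pressure 3. Over all arrays the log2 fold changes of hsp-16.2, hsp-16.41 and hsp-70 were −1.09 ± 2.37, −1.03 ± 1.87 and −0.56 ± 1.84. Within slide 2 they were 0.46 ± 0.23, 0.37 ± 0.22 and 0.96 ± 0.23. None of the 24 measured cytosolic heat shock genes passed the test, over all genes or adjusted over the list alone. The list's median log2 fold change was −0.32 over all arrays (camera adjusted p = 0.0959) and 0.083 within slide 2 (adjusted p = 0.297), and it passed as lower without pressure 1 (adjusted p = 0.00663) and without pressure 2. The constitutive chaperone hsp-1 had −0.42 ± 0.34. The endoplasmic reticulum chaperone hsp-4 and the mitochondrial chaperone hsp-6 had −0.15 ± 0.38 and −0.061 ± 0.24. None of 23 endoplasmic reticulum stress genes (median −0.12, camera adjusted p = 0.264) and none of 15 mitochondrial stress genes (median −0.061, adjusted p = 0.477, above the median of all genes with quantile normalization) passed. As a list the endoplasmic reticulum genes passed in 1 of 19 alternatives of the camera test, and the mitochondrial genes in 0.

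DAF-16 target genes did not pass the test as a list. Of 21 measured genes that DAF-16 induces, 12 were higher and 9 lower, with a median of 0.044 (camera adjusted p = 0.499, below the median of all genes with normexp background correction). The superoxide dismutase gene sod-3 had a log2 fold change of 0.21 ± 0.39 and the metallothionein genes mtl-1 and mtl-2 had −0.80 ± 0.36 and −0.30 ± 0.28. The cadmium-responsive gene cdr-2 had 1.34 ± 0.41. The 11 measured DAF-16-repressed genes had a median of −0.050 (adjusted p = 0.669). The gene daf-16 itself was lower on all 3 pressure arrays than on both controls, at −0.44 ± 0.20, and did not pass. Transcripts of hsf-1, skn-1, hif-1 and pmk-1, which encode the regulators of heat shock, oxidative stress, hypoxia and immune responses, had −0.26 ± 0.29, −0.28 ± 0.24, 0.095 ± 0.44 and 0.094 ± 0.29.

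Genes for stress kinases and AP-1 were among the regulators with the lowest p. The log2 fold change of jun-1, which encodes an AP-1 transcription factor, was 0.61 ± 0.18, and that of kgb-2 was 1.08 ± 0.21. The kinase gene kgb-1 had 0.93 ± 0.37 and the factor klf-3 had 0.95 ± 0.38, while fos-1 had 0.13 ± 0.18. The pressure arrays of all 5 genes lay above both controls. Over the whole regulator list this held for 7 members, while 5 members had all pressure arrays below both controls. None of the 39 immediate early and stress regulators passed over all genes or adjusted over the list alone, and the list split into 20 higher and 19 lower (median 0.014 and mean 0.055 against a downward test, camera adjusted p = 0.877, below the median of all genes with quantile normalization).

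**Figure D2:**
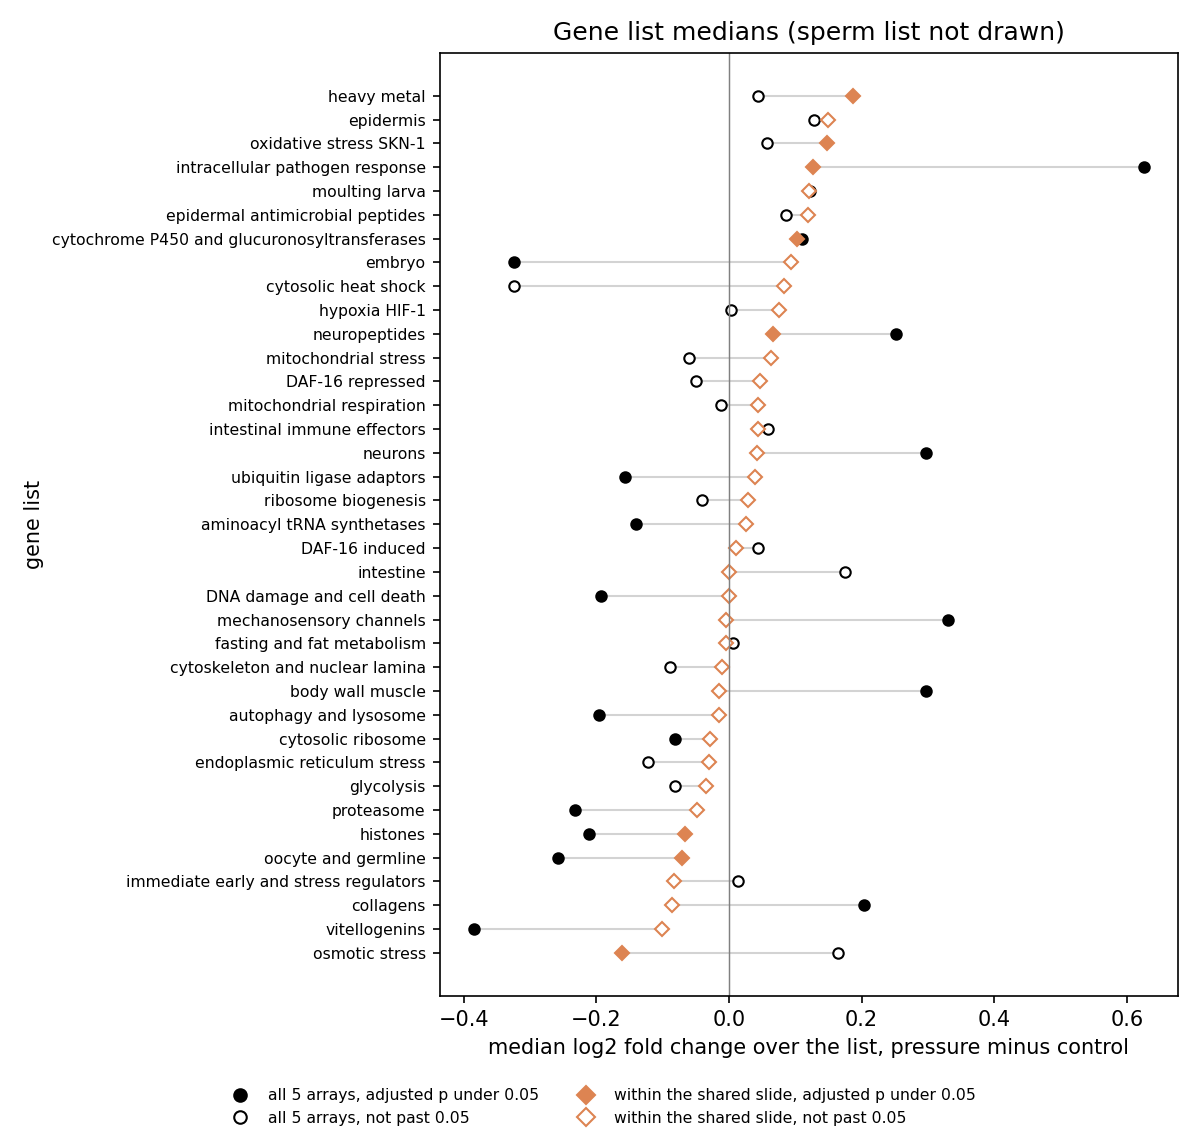
Median log2 fold change, pressure minus control, of 37 gene lists over all 5 arrays (circles) and within slide 2 (diamonds); filled symbols passed camera with a preset correlation at an adjusted p of 0.05. Most lists lie closer to 0 within slide 2, and none passed with an estimated correlation.

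Genes of the intracellular pathogen response, which animals switch on during microsporidian and viral infection, rose as a list. Of 31 measured members 26 were higher after pressure, and the median log2 fold change was 0.63 (camera adjusted p = 4.04e-06). Control 2 was itself above control 1 by a median of 0.69. Relative to gene means, the list was at −0.63 on control 1, 0.074 on control 2 and 0.12 to 0.31 on the pressure arrays. Much of the rise thus rests on control 1. With an estimated correlation the list had an adjusted p = 0.801, and within slide 2 its median was 0.13 with an adjusted p = 0.0187, or 0.964 with an estimated correlation. Members with the lowest p were pals-26 at 0.94 ± 0.20, pals-39 at 1.73 ± 0.46, B0507.8 at 1.53 ± 0.50 and pals-27 at 0.65 ± 0.22, and no member passed over all genes or adjusted over the list alone. Without control 1 the list's median was 0.089 (adjusted p = 0.0403), the lowest of the 19 alternatives, all of which called it. Intestinal immune effectors did not pass as a list (40 measured, median 0.058, adjusted p = 0.553). A single member, the infection response gene irg-2, passed when adjusted over the list alone, at a log2 fold change of 1.88 ± 0.26, and 0 passed over all genes. The lysozyme gene lys-3 had 1.72 ± 0.51. Epidermal antimicrobial peptides had a median of 0.086 (19 measured, adjusted p = 0.326), with cnc-11 at 0.61 ± 0.21 and nlp-29 at 0.11 ± 0.23. That list passed in 1 of the 19 alternatives.

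Several detoxification lists were higher on the pressure arrays of slide 2, which holds a single control array. Cytochrome P450 and glucuronosyltransferase genes rose as a list over all arrays (131 measured, 83 higher, median 0.11, camera adjusted p = 0.0484) and within slide 2 (median 0.10, adjusted p = 0.00725, and 0.964 with an estimated correlation). With an estimated correlation the adjusted p = 0.801 over all arrays, and the list did not pass without control 2, pressure 1 or pressure 2. The test fry, which asks whether a list moves on balance one way, gave this list an unadjusted p = 0.00701 and an adjusted p = 0.266. The lowest-p members were ugt-16 at 1.19 ± 0.24 and cyp-33C8 at 1.57 ± 0.33. Oxidative stress genes of the SKN-1 pathway did not pass over all arrays (37 measured, median 0.057, adjusted p = 0.417) and rose within slide 2, where 30 were higher (median 0.15, adjusted p = 0.0051, and adjusted p = 0.964 with an estimated correlation). Between pressure 3 and control 1, on the other slides, the median difference was −0.092. Thioredoxin gene trx-1 had 1.04 ± 0.20 and the glutathione S-transferase gene gst-4 had 0.31 ± 0.49 over all arrays and 0.61 ± 0.11 within slide 2, and was −0.43 on pressure 3 relative to control 1. The glutathione synthesis gene gcs-1 had 0.15 ± 0.18. Heavy metal genes likewise passed only within slide 2 (15 measured, median 0.19, adjusted p = 0.0198, and 0.964 with an estimated correlation, against 0.044 and 0.499 over all arrays and a median of −0.28 between pressure 3 and control 1), and numr-1 had 0.91 ± 0.42. Osmotic stress genes fell within slide 2 (23 measured, median −0.16, adjusted p = 0.0494, and 0.964 with an estimated correlation, against a median of 0.44 between pressure 3 and control 1), where the inositol transporter gene hmit-1.3 had −0.85 ± 0.10. Over all arrays that list had a median of 0.16 and a mean of 0.11 against a downward test (adjusted p = 0.877), and gpdh-1, a glycerol synthesis gene, had 1.00 ± 0.83. Hypoxia genes had a median of 0.0033 and a mean of −0.071 (16 measured, downward test, adjusted p = 0.714, below the median of all genes with normexp background correction), with nhr-57 at 0.22 ± 0.57 and gbh-2 at −0.86 ± 0.30.

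Cuticle collagens included col-17 and lon-3 of the 16 genes named first, the 8 lowest-p genes in each direction without overlap. Of 164 measured collagens, 97 were higher and 67 lower, and the list rose over all arrays (median 0.20, camera adjusted p = 0.00664), with an adjusted p = 0.801 with an estimated correlation. Within slide 2 the median was −0.085 and 56 were higher (adjusted p = 0.281), so the list's direction turned, as it did without control 1 (median −0.10, adjusted p = 0.819). Collagens were among the lists that set control 1 apart from control 2. The members with the lowest p were col-17, lon-3, col-49 and bli-1, and 3 collagens, col-17, lon-3 and col-49, passed when adjusted over the list alone, against 0 over all genes. Neither col-49 nor the blister collagen gene bli-1 was well above background on any control, and they were at least 27.8-fold and at least 6.87-fold higher. The collagen gene rol-6 had 4.01 ± 0.93. Moulting genes did not pass (30 measured, median 0.12, adjusted p = 0.0895), nor did epidermal genes (25 measured, median 0.13, adjusted p = 0.228). The moulting list passed as higher without control 1, pressure 1 or pressure 2 and the epidermal list without control 1, and both medians were below 0 without control 2 and without pressure 3. Among them the hedgehog-related gene wrt-6 had 1.67 ± 0.58 and the epidermal STAT factor gene sta-2 had 1.82 ± 0.39.

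**Figure D3:**
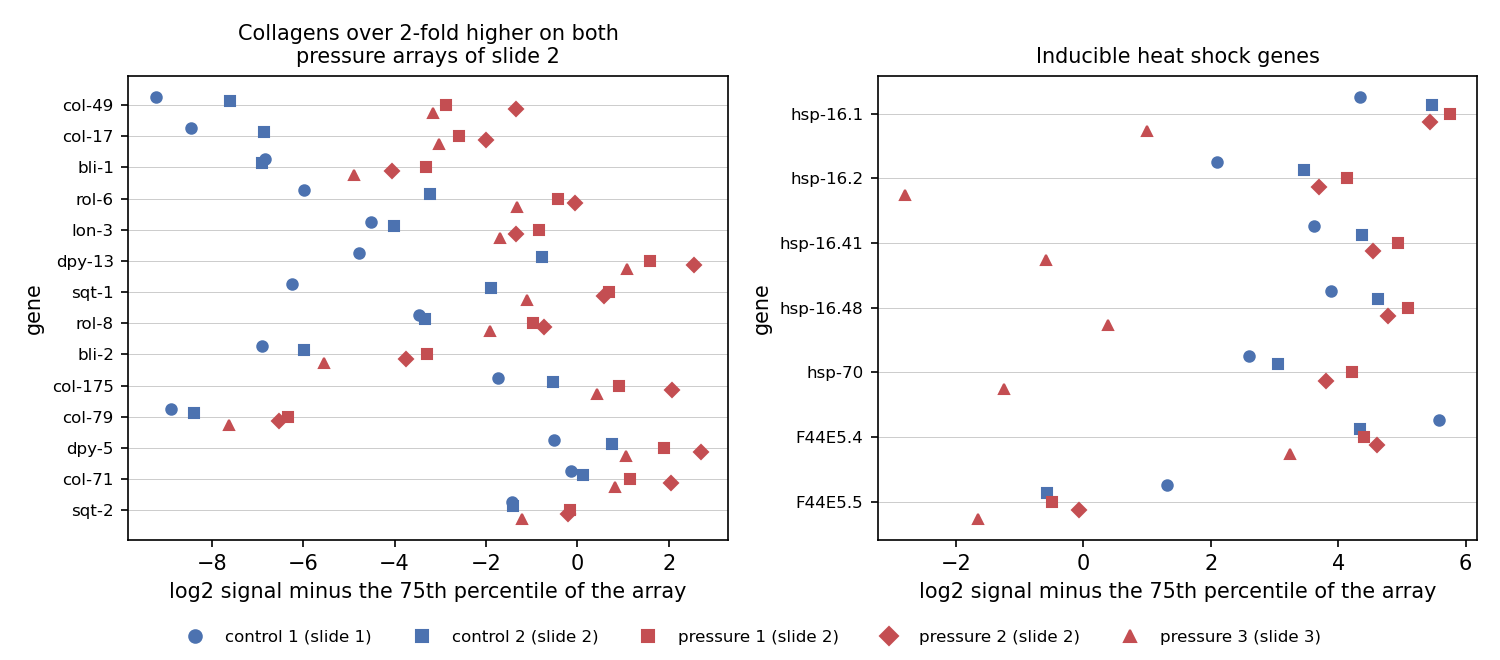
Log2 signal on each array, relative to the array's 75th percentile, of 14 collagens over 2-fold higher on both pressure arrays of slide 2 than on control 2 (left) and of 7 inducible heat shock genes (right). Of the heat shock genes 5 lie over 4-fold below every other array on pressure 3.

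Germline and proteasome genes were lower after pressure over all arrays. Of 46 oocyte and germline genes 45 were lower, with a median of −0.26 (camera adjusted p = 7.34e-09), and 30 of 33 proteasome genes were lower, with a median of −0.23 (adjusted p = 4.04e-06). Both lists had an adjusted p = 0.801 with an estimated correlation, as did the 4 lists that follow. Histone genes fell too (46 of 54 lower, median −0.21, adjusted p = 3.21e-05), as did DNA damage and cell death genes (18 of 22, median −0.19, adjusted p = 0.00236), autophagy and lysosome genes (23 of 28, median −0.20, adjusted p = 0.0157) and aminoacyl tRNA synthetases (29 of 34, median −0.14, adjusted p = 0.0152). The median of control 2 minus control 1 was −0.55 for histones, −0.34 for DNA damage, −0.32 for autophagy and −0.052 for tRNA synthetase genes. Relative to gene means, histones were at 0.42 on control 1, −0.12 on control 2 and −0.19 to 0.019 on the pressure arrays. The histone, DNA damage and autophagy falls thus rest largely on control 1. So does much of the germline fall, where the median of control 2 minus control 1 was −0.30. Germline genes were at 0.36 on control 1, −0.00099 on control 2 and −0.17 to −0.045 on the pressure arrays. For proteasome genes that median was −0.22. They were at 0.24 on control 1 and −0.27 on pressure 3, with the other arrays between −0.042 and 0.028. Vitellogenins (6 of 6 lower, median −0.38, adjusted p = 0.0265), embryo genes (25 of 29, median −0.32, adjusted p = 0.027) and ubiquitin ligase adaptors (247 of 374, median −0.16, adjusted p = 0.0309) completed the lower lists, with cytosolic ribosomal protein genes (62 of 75, median −0.081, adjusted p = 0.0486), whose direction turned with quantile normalization. These 4 had an adjusted p between 0.801 and 0.859 with an estimated correlation. No member of the 10 lower lists passed over all genes or adjusted over the list alone. Examples were gld-1 at −0.39 ± 0.19, mex-5 at −0.64 ± 0.30, rpn-1 at −0.49 ± 0.24 and his-47 at −0.82 ± 0.39. Within slide 2 the medians were −0.071 for germline genes (adjusted p = 0.0104) and −0.067 for histones (adjusted p = 0.0412), both with an adjusted p = 0.964 with an estimated correlation. Those p-values hold no spread between controls, so control 2 alone could set shifts of this size. There the other 8 did not pass, and the embryo, tRNA synthetase and ubiquitin ligase adaptor lists had tests in the other direction. Without control 1, where control 2 is the single control and is assumed to vary like the pressure arrays, the embryo median was 0.49. Pressure 3 carried it, at 0.68 relative to each gene's mean over the 5 arrays against −0.71 on control 2, −0.73 on pressure 1 and −0.29 on pressure 2, so it follows the slides. In that fit the ubiquitin ligase adaptors had a median of 0.076 (adjusted p = 0.481), and of the 10 lists only the germline, proteasome and ribosome lists passed as lower. The ribosome list rose without pressure 3 (median 0.16, adjusted p = 0.00624) and had a median of 0.078 without control 2. The tRNA synthetase and vitellogenin lists did not pass without control 2 or without pressure 3. The autophagy, embryo and ubiquitin ligase adaptor lists did not pass without pressure 1, the first 2 of these did not pass without pressure 2, and the adaptors did not pass without pressure 3. The apoptosis activator egl-1 had −0.53 ± 0.45.

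Sperm, muscle and neuronal genes rose as lists over all arrays. Sperm, body wall muscle and neuropeptide genes were lowest on control 1, with a median 0.68 higher on control 2 for muscle and 0.60 for neuropeptides. Neuron and mechanosensory channel genes were highest on pressure 3, with medians 0.84 and 0.86 above control 1. Sperm genes had a median log2 fold change of 3.13 (66 of 70 higher, camera adjusted p = 2.44e-08) and a median of −0.092 within slide 2, against the single control array (adjusted p = 0.0104). Its adjusted p with an estimated correlation was 0.801 over all arrays and 0.964 within slide 2. The other lists that rose were neuropeptides (78 of 91, median 0.25, adjusted p = 4.04e-06), mechanosensory channels (30 of 34, median 0.33, adjusted p = 6.84e-05), neurons (30 of 38, median 0.30, adjusted p = 0.000976) and body wall muscle (32 of 41, median 0.30, adjusted p = 0.0023). With an estimated correlation each had an adjusted p = 0.801. Of these, neuropeptides also passed within slide 2 (median 0.067, adjusted p = 0.0349, and 0.964 with an estimated correlation), and body wall muscle had a median of −0.015 there. Without control 1 the sperm median was −0.85, again against control 2 alone. It follows the slides too, with pressure 3 at −0.27 relative to each gene's mean over the 5 arrays and the arrays of slide 2 at 1.9 to 2.2. In that fit the muscle, neuropeptide and mechanosensory lists did not pass (medians −0.097, −0.014 and 0.15). Without pressure 3 the neuron and mechanosensory lists did not pass, nor did the neuron list without control 2. The insulin-like gene ins-14 had 0.93 ± 0.30 and the touch channel genes mec-10 and mec-4 had 0.69 ± 0.22 and 0.79 ± 0.33. The myosin gene unc-54 had −0.018 ± 0.22 and the actin gene act-1 had −0.19 ± 0.20.

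Metabolic and structural lists did not pass over all arrays or within slide 2. Medians over all arrays were 0.0066 for 47 fasting and fat metabolism genes (camera adjusted p = 0.553), −0.082 for 19 glycolysis genes (0.466), −0.012 for 46 mitochondrial respiration genes (0.499), −0.040 for 25 ribosome biogenesis genes (0.417), −0.089 for 50 cytoskeleton and nuclear lamina genes (0.228) and 0.17 for 29 intestine genes (0.149), each an adjusted p. The means were −0.077 for fasting, 0.092 for glycolysis and 0.041 for mitochondrial respiration genes, opposite in sign to their medians, and all 3 tests pointed down. Mitochondrial respiration genes passed in both directions when an array was left out, as higher without pressure 3 (median 0.19, adjusted p = 0.00886) and as lower without control 1 (median −0.15, adjusted p = 0.022) and without pressure 1 (median −0.13). With the replicate number as a block, which leaves pressure 3 out of the contrast, the list passed as higher (adjusted p = 0.0394). The intestine list passed as higher without control 2 (adjusted p = 0.0303) and with quantile normalization (adjusted p = 0.0112). Of these, all but the fasting and intestine lists lay above the median of all genes with quantile normalization, and the fasting list lay below it with normexp background correction. The lysosomal lipase genes lipl-1 and lipl-2 and the fasting-induced gene fil-2 were lower on all 3 pressure arrays than on both controls, at −2.83 ± 0.94, −2.14 ± 0.60 and −2.26 ± 0.78, without passing. The intermediate filament gene ifd-2 of the intestine had 1.92 ± 0.54.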

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

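The alternatives were chosen before the data were examined, apart from 2 chosen after seeing the data: adding the probes that match no gene, and counting the fixed slide block at an adjusted p under 0.1. With 5 arrays, 2 of them controls, the count of genes past the threshold was 0 in every fit run except that with slide as a random block. That fit called 35 genes, 28 higher and 7 lower, 34 of them by at least 2-fold; the cause was not tested. In the plain two-sample test 417 genes had an unadjusted p under 0.05. At an adjusted p under 0.1 the fixed slide block counted 61 genes, and adding the probes without a gene that passed the filter, for 20829 tested in all, left the count at 0, with 487 at an unadjusted p under 0.05. Median scaling moved the median of all genes by −0.20 in log2, and camera compares each list with the other genes. Of the 182 named genes, 146 kept their direction in all alternatives that gave a value. Signal over background limits the genes that are dim in a group, whose folds are bounds, and normexp with an offset of 50 drew them towards 0, as its offset does by construction.

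Of the 38 list tests, 18 passed over all arrays, 9 with slide as a fixed block and in the same comparison within the shared slide, 8 with slide as a random block, 0 with an estimated correlation, 0 with fry, and between 11 and 17 when 1 array was left out; the cause was not tested. Within the shared slide and without either control, 1 control array is left and is assumed to vary like the pressure arrays. The intracellular pathogen response and the germline list were called in the same direction in all 19 alternatives of the preset-correlation test. The direction of the list test turned as follows in lists that passed in either fit, and the cause was not tested. With quantile normalization the cytosolic ribosome list had a median of 0.030. With slide as a fixed block and within the shared slide the medians were 0.026 for aminoacyl tRNA synthetases, −0.085 for collagens, −0.092 for sperm, 0.094 for embryo, −0.015 for body wall muscle and 0.039 for ubiquitin ligase adaptors. With slide as a random block they were −0.066 for collagens and 0.055 for embryo. When each array was left out in turn, the medians ran from −0.26 to 0.16 for the cytosolic ribosome, −0.10 to 0.57 for collagens, −0.85 to 7.29 for sperm, −1.22 to 0.49 for embryo, −0.10 to 0.54 for body wall muscle, −0.15 to 0.19 for mitochondrial respiration and −0.30 to 0.076 for ubiquitin ligase adaptors. The sign of the median changed more widely: only the intracellular pathogen response, proteasome, histone, vitellogenin, germline and neuron lists kept it in all alternatives. Over these the medians ran from −0.52 to 0.087 for cytosolic heat shock, −0.18 to 0.28 for osmotic stress, −0.014 to 0.54 for neuropeptides, −0.26 to 0.55 for the moulting list and −0.21 to 0.30 for epidermis.

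The samples of the groups share only a number, and it is not stated to mark pairs. Across genes, the deviations of control 1 and pressure 1 from their group means correlated at r = −0.588, and those of control 2 and pressure 2 at 0.576. The deviations of the controls mirror each other, and control 2, pressure 1 and pressure 2 share slide 2. These values therefore cannot show whether the numbers pair the samples. With the replicate number as a block 0 genes passed in limma (195 at an unadjusted p under 0.05) and 14 lists did. The ribosome list then passed as higher, opposite to its call over all arrays (median 0.16), and so did the mitochondrial respiration list (median 0.19), each at an adjusted p = 0.0394.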

Other observations

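All gene families below were chosen after the data were examined, as were 4 tests on the 3 patterns that follow them: sperm content alone, control 2 alone, moulting larvae, and heat or handling stress. Glutathione S-transferase genes, 11 of whose 41 measured members sit in the fixed lists, were higher on the pressure arrays of slide 2. There 36 of 41 were higher, with a median log2 fold change of 0.19 (camera adjusted p = 5.18e-05 over 224 families), and over all arrays the median was 0.18 (adjusted p = 0.0388). The adjusted p with an estimated correlation was 0.982 within slide 2 and 0.825 over all arrays. The rise within slide 2 rests on control 2 as the single control array, and the median between pressure 3 and control 1 was −0.034. Tetraspanin genes (21 measured) had medians of 0.49 over all arrays (adjusted p = 0.00013) and 0.15 within slide 2, where 17 were higher (adjusted p = 0.0104). They and the next 2 families had an adjusted p = 0.825 over all arrays and 0.982 within slide 2 with an estimated correlation. Globin genes (32 measured) had 0.52 (adjusted p = 4.24e-06) and 0.18 (adjusted p = 0.028), and P-glycoprotein transporter genes (14 measured) had 0.60 (adjusted p = 0.00242) and 0.19 (adjusted p = 0.0463), and did not pass without control 1 (adjusted p = 0.0551). In all, 39 families passed over all arrays and 10 within slide 2, with 6 in both and in the same direction. With an estimated correlation none passed in either comparison.

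The abu genes, which encode proteins first described as activated in blocked unfolded protein response, differed between slides. On the pressure arrays of slide 2, 2 of the 13 measured members were higher, and the median was −2.3 (adjusted p = 0.028, and 0.982 with an estimated correlation). Pressure 3 was higher than control 1 by a median of 2.99, so over all arrays the median was 0.036 (adjusted p = 0.762).

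Control 1 and pressure 3 stood apart from the 3 arrays of slide 2. Of the 10 splits of the arrays into 2 and 3, that split called 2708 genes and each of the others 0, the split by pressure included; it called 3345 after quantile normalization, which argues against overall brightness or scaling. In 598 genes with 2 probes that do not overlap, the control 1 minus control 2 differences of the probes correlated at r = 0.721 across genes, which argues against hybridization faults of single probes. In the test of sperm content alone, 3 of 3 lists of other tissues differed by over 0.3 between the controls. The difference was thus not confined to sperm genes. Those lists and that limit were chosen after the data were examined, so their outcome was not open. Relative to gene means, the sperm list was at −5.24 on control 1 and −0.27 on pressure 3, against 1.9 to 2.2 on slide 2. The embryo list was at 1.48 and 0.68 on them, against −0.73 to −0.29 on slide 2. Such opposite shifts of whole tissue lists argue against the slide alone for these lists. The age or culture of the animals and the RNA preparation stay open, as does the slide for other genes, since each solitary array has its own slide.

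A set of 14 collagens was over 2-fold higher on both pressure arrays of slide 2 than on control 2, and 4 collagens were over 2-fold lower on both. Of 10000 random lists matched to the collagens, 0 held as many higher genes (highest 8), which argues against independent noise of single genes as chance among the measured collagens, but not against a shared shift of co-regulated collagens on 1 array. An odd level on control 2 alone cannot be told apart from a difference after pressure: on the other slides the set's median was 2.06 higher on pressure 3 than on control 1, against 0.89 for all collagens, but 581 of 10000 random collagen sets of like signal reached it (287 without that matching). All 14 were higher on pressure 3 than on both controls, and 13 were higher on control 2 than on control 1, the array on which collagens as a list were lowest. Moulting larvae among the pressure animals stay open too, as do a response to pressure and handling that the controls did not share: the rest of the moulting list had a within-slide median of 0.089 (28 genes, going both ways), while its member wrt-6 had 1.84 ± 0.14 there and 8 of 9 genes of the wrt family were higher.

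Inducible heat shock genes were lower on pressure 3 than on every other array, the controls included. The median gap between pressure 3 and the lowest other array was 3.51 in log2, and 3.42 after quantile normalization, which argues against overall brightness or scaling. In 5 of 7 members the gap was over 4-fold, against 0.297% of all genes, which argues against a single probe or gene. Probes of hsp-16.1, hsp-16.48, F44E5.4 and F44E5.5 carried accessions of several loci, so the members are not all independent measurements. Those of hsp-16.2, hsp-16.41 and hsp-70 did not. Heat or handling stress of the animals on the other arrays stays open. Of 17 other cytosolic heat shock members 11 were lowest on pressure 3, with gaps up to 0.67 for hsp-1. Of 10000 random lists matched on signal, 2442 had as many, and the median gap over the 17 was 0.157. The 4 members over 1 log2 unit above their lowest other array on pressure 3 were hsp-12.1, hsp-12.2, hsp-12.3 and hsp-12.6. Whether heat induces each of the 17 was not examined, so the pooled list cannot decide. Among the 3 pressure samples, the labels record no difference in handling or recovery.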
